A study of Mus musculus with 2 samples.

How the data were processed

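Single-cell 5' gene expression and T cell receptor (TCR) libraries were made with 10x Genomics reagents from the same sorted population, per the labels' protocols. CD8+ T cells from wild-type mice immunized with a mixture of self-reactive peptides were stained with CellTrace Violet, a dye diluted at each division, and stimulated again with the peptides in culture. Cells positive for CD44, a marker of antigen-experienced T cells, and low in CellTrace Violet, and so divided, were sorted. The series held 1 gene expression library and 1 TCR library, with no unstimulated, unsorted or non-immunized group and no replicates. No significance test was therefore run and no p-value is given, and percentiles among random lists only describe these libraries.

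The deposited matrix holds raw UMI counts per gene and cell barcode, not normalized, made with Cell Ranger per the submitters' processing notes. Its header gives software version 3.1.0. The genome build, the gene annotation and the V(D)J reference are not given in the sources used here, so genes are named as the files name them and no coordinates are given. The matrix listed 13773 barcodes and 21823 genes, of which 14935 had a UMI, and only 1 of them was a TCR gene. The deposited TCR table lists every assembled contig with its counts of UMIs and reads, its V and J genes, its CDR3 sequence, and whether Cell Ranger called the barcode a cell, per the file headers. It held 69947 contigs in 22345 barcodes. Gene expression and TCR were joined by barcode.

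Barcodes with under 500 genes (62) or with 10% or more mitochondrial UMIs (110) were left out, and 13654 passed both filters. Scrublet in scanpy 1.11.5, with 6% expected doublets and its automatic threshold of 0.631, marked 0 barcodes, so it has not worked on these data. Doublets were removed only by the TCR: 867 barcodes with 2 or more productive TRB chains of 2 or more UMIs each were left out, which left 12787 cells. This rule reads only barcodes that Cell Ranger called cells in the TCR table, and doublets remain among the others. Genes seen in fewer than 3 cells were left out of clustering. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without TCR genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 0.6 with seed 0 (leidenalg 0.10.2). Clusters are numbered by size. A cluster was called by a cell state only from markers fixed before the data were examined, and cluster 11 and others with leading genes of several lists kept their number.

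A paired cell had at least 1 productive TRA and 1 productive TRB contig of high confidence. A clonotype was the same nucleotide CDR3 and V gene of the TRA and of the TRB contig with most UMIs. Clonotypes of 1 cell are called single, those of 2 to 4 cells small, and those of 5 or more cells expanded. Shares have exact (Clopper-Pearson) 95% binomial intervals. Levels are summed counts as CPM, scaled to the same total of UMIs in each group, with exact Poisson intervals, and ratios of CPM have conditional binomial intervals. All of these cover counting error only, not differences between mice or cultures. Where 0 cells had a UMI or a chain pair, the limit on the share is that of 3 counts. The ratio was tested on simulated counts for expanded against single cells with 8604 genes. Its interval covered the known ratio for 98% of 100 genes changed 2-fold, 97% of 100 genes changed 4-fold and 94.9% of 8404 unchanged genes. The simulated counts were Poisson draws of each group's total, without variation between cells or clonotypes. They therefore check only the calculation, and say nothing of coverage in real cells.

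Genes were named by rules fixed before the data were examined. For each fixed list these were up to 4 members with the largest ratio between clusters of at least 100 cells, among members of 20 CPM or more. For expanded against single cells these were the 15 highest and the 15 lowest ratios among genes of 50 CPM or more in either group. Their direction had to hold with each clonotype weighted equally, without the largest clonotype and in both random parts of the clonotypes, and TCR, ribosomal protein, mitochondrial, Gm and Rik genes were left out. This left 2753 eligible genes out of 3160. Results of some genes that these rules name are not reported here. The 5 most used V genes of each chain and the 10 largest clonotypes were named. The lists covered markers of CD8 and CD4 T cells, B, plasma, NK, gamma-delta T, NKT, dendritic, granulocyte, erythroid and platelet lineages, and monocytes or macrophages. They also covered both cell cycle phases, cytotoxic effector, memory or naive, inhibitory receptor, interferon response, regulatory CD8, resident memory and innate-like receptor genes. Further lists held activation, cytokine, chemokine, virtual memory, glycolysis, p53 and death, stress, and T cell fate transcription factor genes. Another list joined TCR-induced genes, such as the Nr4a and Egr genes, with tolerance-associated genes. A list's median log2 ratio over members of 5 CPM or more was set beside 10000 random lists of the same size matched on expression.

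For shares of cells with a UMI, cells were also thinned to 3000 UMIs. Alternatives fixed beforehand changed the mitochondrial limit, the doublet treatment, the clustering resolution, the cell cycle genes, the CPM total, the contig UMIs, the clonotype definition and the weighting of clonotypes. Others were added after the data were seen: the highest Scrublet scores left out, TRB contigs of any confidence for doublets and for clonotypes, clonotypes without V genes, clusters 10 and 11 left out, and the Ly49 genes of the regulatory CD8 list summed as 1 member or left out. The levels in small clonotypes, and the small clonotypes on both sides of the clusters, were also taken up then. The summed regulatory CD8 list was first used as the value for expanded against single cells, and its median was put in its place after both were seen.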

Results

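The series measured the transcriptomes and paired TCRs of divided, CD44+ CD8+ T cells that had met self-peptides in immunized mice and again in culture, to describe the transcriptional features and clonotypes of such cells. The gene expression library held 181849104 UMIs in 13773 barcodes. A barcode had a median of 9513 UMIs, from 502 to 99647, and 2749 genes, and its median mitochondrial share was 1.22%. The 12787 cells analysed had a median of 9389 UMIs and 2729 genes. Each kind of library was made once, so no value below has a replicate, and all intervals cover counting error only.

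The cells fell into 11 transcriptional clusters, from 3619 cells (28.3%, 95% interval 27.5 to 29.1) to 30 cells. Cluster 1 was led by Hcst, Ccl5, Il7r, Klf2 and S1pr1, the last 3 of which are found in resting and recirculating T cells. Cluster 2 (15.4%) was led by histone genes, and cluster 7 (7.62%) by Ccnb2, Cdc20, Cenpf and Ube2c and was called G2/M-like. Cluster 3 (13.5%) was led by Xcl1, a chemokine for cross-presenting dendritic cells, and by Chchd10, Eno3 and Id3. Cluster 4 (8.95%) was led by Batf3, Lta and Ifitm3, cluster 5 (8.16%) by Asb2, Mmp9, Ckb and Tmem176a, and cluster 6 (8.10%) by the cell cycle inhibitors Cdkn2b, Cdkn2a and Cdkn1a. Cluster 8 (6.16%) was led by the granzymes Gzma and Gzmk with Ccl5, Ccl4, Prf1 and Gzmb and was called cytotoxic effector-like. Cluster 9 (3.32%) was led by genes that included Tcf7, Ikzf2 and Klra7, of which Ikzf2 encodes Helios. Cluster 10 (36 cells) was led by Foxp3 and Ctla4, and cluster 11 (30 cells) by Cd74, H2-Aa, Mzb1, Cd79a and Ms4a1, genes of antigen presentation and of the B lineage. Median depth differed between clusters, from 4987 UMIs in cluster 1 to 29067 in cluster 3.

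The fixed lists followed the clusters, which were made from the same expression values, so their levels describe the clusters and test nothing. CD8 T cell markers summed to 3089 CPM or more in clusters 1 to 10, against 1012 CPM (911 to 1121) in cluster 11, where B cell markers reached 2684 CPM and dendritic cell markers 10232. Among clusters 1 to 9, B cell markers stayed at 32.3 CPM or less and granulocyte markers at 5.58 or less. Cytotoxic effector genes summed to 16967 CPM in cluster 8 and to 1742 CPM in cluster 9. In cluster 8 Gzma stood at 3508 CPM, Ccl4 at 450 and the inhibitory receptor Havcr2 at 99.8. S phase genes were highest in cluster 2 at 3557 CPM and were 3126 CPM in cluster 3, whereas G2/M genes were 4729 CPM in cluster 2 and 4529 in cluster 7. The p53 and death list was highest in cluster 6 (2069 CPM), with Cdkn1a at 536 CPM there. Memory or naive genes (2525 CPM) were highest in cluster 9 among clusters 1 to 9. So was the joint list of TCR-induced and tolerance-associated genes (1249 CPM). Of that list, Nr4a1, an early gene of TCR signalling, stood at 211 CPM and Cblb, a negative regulator of TCR signalling, at 164. Among clusters 1 to 9 activation genes were highest in cluster 3 (1660 CPM, with 5849 in cluster 10), with Tnfrsf9 at 433 and Myc at 174. Interferon response and resident memory genes were highest in cluster 5 (880 and 1733 CPM) among clusters 1 to 9, with Cxcr6 at 1428. The regulatory CD8 list was 1066 CPM in clusters 3 and 9 together against 823 in clusters 1, 2, 4, 5, 6 and 7, a ratio of 1.30 (1.28 to 1.31).

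Of the 12787 cells, 9947 had a paired TCR, 77.8% (77.1 to 78.5). The pairing share was lowest in cluster 3 among the 9 largest clusters, at 63.4%, and highest in cluster 1, at 83.6%. The main TRA contig had a median of 11 UMIs and the main TRB contig 24. The paired cells made up 1925 clonotypes. The 257 expanded clonotypes held 7818 cells, 78.6% of the paired cells (77.8 to 79.4), the 299 small clonotypes held 760 cells (7.64%), and the 1369 single clonotypes 13.8% (13.1 to 14.5). The largest clonotype had 587 cells, 5.90% (5.45 to 6.38), and the 10 largest together 2435 cells, 24.5% (23.6 to 25.3). The Gini coefficient of clonotype sizes was 0.751 and their Shannon evenness 0.772. The TRAV11 and TRAJ18 pair of invariant NKT cells and the TRAV1 and TRAJ33 pair of mucosal-associated invariant T cells were each found in 0 paired cells, which allows a share of up to 0.0302%.

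Clonal expansion divided the clusters. In clusters 3 and 9, 6.22% of paired cells (5.03 to 7.60) belonged to expanded clonotypes, against 93.5% (92.9 to 94.0) in clusters 1, 2, 4, 5, 6 and 7. Cluster 3 had 7.69% expanded (6.18 to 9.43) and 74.8% single cells (72.2 to 77.4), and cluster 9 had 1.48% expanded (0.483 to 3.43) and 86.4% single cells (82.2 to 89.8). The cytotoxic effector-like cluster 8 lay between, with 56.9% expanded (52.9 to 60.9) and 18.05% single cells (15.1 to 21.3). Clusters 3 and 9 held 16.8% of all cells, 81.0% of the single cells (1109) and 1.14% of the expanded cells (89). In cluster 6, 97.5% of paired cells were expanded and 0.123% single. When clonotypes of 2 cells or more were counted as expanded, the share in clusters 3 and 9 was 22.4%. Clusters 3 and 9 were put together after these shares were seen, and they differed in second TRB contigs. Of cells with a TRB contig, 30.4% in cluster 3 (28.2 to 32.6) and 14.2% in cluster 9 (11.002 to 17.9) had 2 or more TRB contigs of any confidence, against 6.79% to 19.7% in clusters 1, 2, 4, 5, 6 and 7. These are not shares of paired cells. In cluster 3 they cover 1714 cells with a TRB contig, of which the expanded and single shares above used the 1093 paired ones. Barcodes not called cells in the TCR table, which had no paired TCR, are counted among the 1714.

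**Figure D1:**
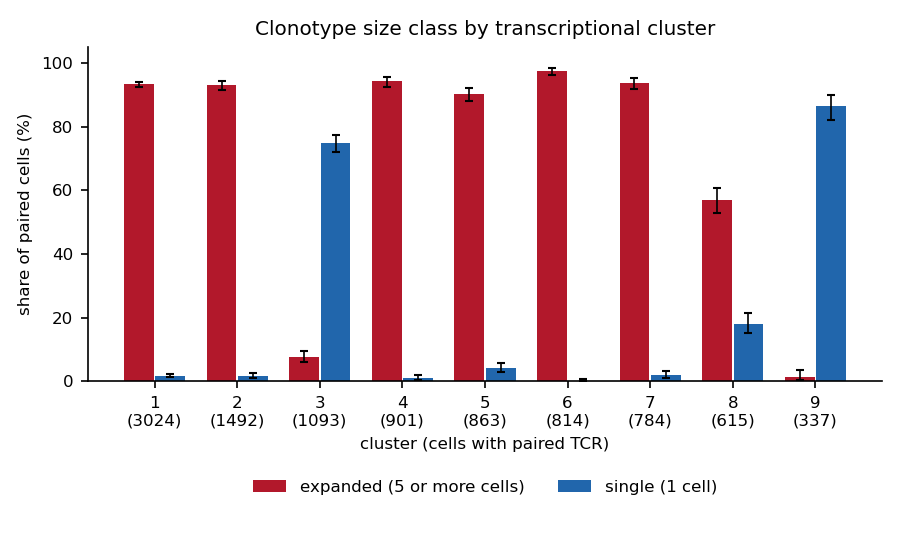
Share of paired cells in percent (vertical axis) that belonged to expanded clonotypes (5 or more cells) or to single clonotypes, for each transcriptional cluster, with exact 95% binomial intervals as error bars. Expanded cells made up 93.3% of cluster 1 and 1.48% of cluster 9.

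Cells of a clonotype shared their state more often than cluster sizes would give. Over the 556 clonotypes of 2 or more cells, each weighted equally, 45.5% of cell pairs within a clonotype lay in the same cluster, against 15.1% from the cluster sizes. The largest clonotype paired TRAV7D-2 (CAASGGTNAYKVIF) with TRBV31 (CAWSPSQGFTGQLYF) and had 286 cells in cluster 1, 96 in cluster 2 and 57 in the G2/M-like cluster 7. The next paired TRAV12-2 (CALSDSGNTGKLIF) with TRBV12-1 (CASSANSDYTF, 352 cells), and the third paired TRAV7D-2 (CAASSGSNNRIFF) with TRBV12-1 (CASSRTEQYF, 345 cells). The sixth, of 169 cells with TRAV6N-7 and TRBV17 (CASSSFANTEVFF), had more of its cells in cluster 6 (66) than in cluster 1 (29). The other 6 of the 10 largest had 107 to 237 cells, and 3 of these 6 used TRBV12-1. All of the 10 largest had cells in each of clusters 1, 2, 4, 5, 6 and 7, and 0 of their 2435 cells lay in clusters 3 and 9. Among 473 clonotypes with at least 2 cells in the clusters on either side, 331 lay only in clusters 1, 2, 4, 5, 6 and 7, 103 only in clusters 3 and 9, and 39 (8.25%, 5.93 to 11.1) on both sides. Because these sides were put together by their shares of expanded cells, the counts for expanded clonotypes partly restate that choice. Among the 232 small clonotypes in this comparison, whose cells did not count as expanded, 13 (5.60%, 3.02 to 9.39) lay on both sides, where a random spread of their own cells would give 134.

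**Figure D2:**
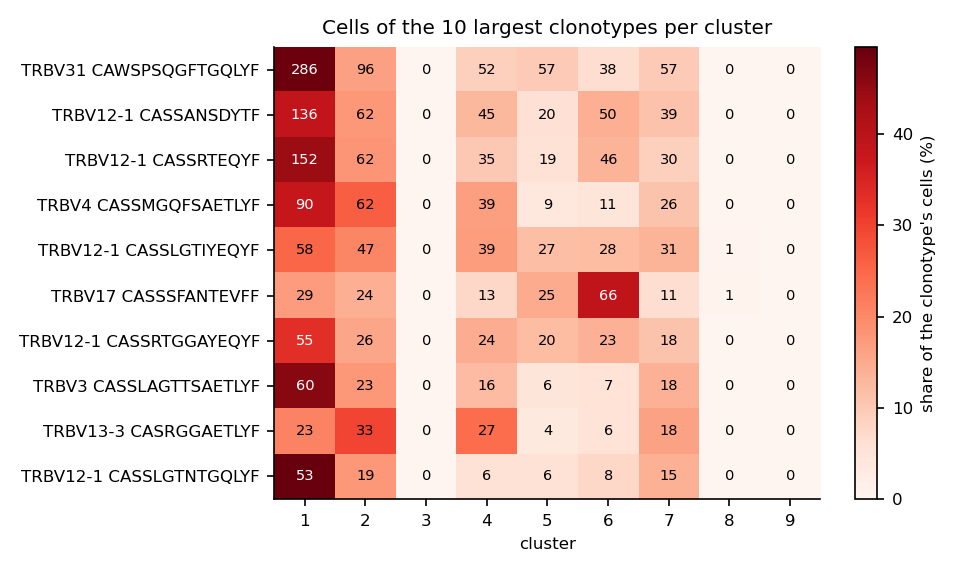
Share in percent (colour) of the cells of each of the 10 largest clonotypes (vertical axis) that lay in each cluster (horizontal axis). Cells of these clonotypes spread over clusters 1, 2, 4, 5, 6 and 7, and clusters 3 and 9 held 0 of them.

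Single cells had far higher levels of Klra7, Id3 and Ccr7, and expanded cells of the Ifitm genes and Cxcr6. In expanded cells the interferon-induced membrane protein genes Ifitm3 (956 against 38.0 CPM, 25.2-fold, 23.7 to 26.8), Ifitm1 (18.9-fold) and Ifitm2 (13.8-fold) were higher. So were Ltb4r1, a leukotriene B4 receptor (20.01-fold), the chemokine receptor gene Cxcr6 (725 against 61.6 CPM, 11.8-fold), Anxa1 (19.0-fold), S100a4 (778 against 47.3 CPM, 16.5-fold), the cell cycle inhibitor gene Cdkn2a (14.6-fold) and Il1r2, which encodes a decoy receptor for interleukin-1 (11.4-fold). In single cells Klra7, a member of the Ly49 receptor family, stood at 91.2 CPM (2574 UMIs) against 0.0787 CPM (6 UMIs) in expanded cells, 1159-fold (532 to 3161). Dapl1 was 134-fold (99.6 to 185), Id3 41.4-fold (37.1 to 46.3), Xcl1 30.9-fold (28.5 to 33.6) and Ccr7, a lymph node homing receptor gene, 25.3-fold higher in single cells. The transcription factor genes Eomes (22.8-fold), Ikzf2 (21.8-fold), Nr4a1 (13.1-fold) and Tcf7 (12.1-fold) were also higher there, as was Izumo1r (41.6-fold), which encodes folate receptor 4.

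The other genes named by the rule were Vax2 (23.7-fold), AA467197 (17.0-fold), Tmem176b (12.8-fold), Podnl1 (12.0-fold), Tmem176a (11.1-fold) and Serpinb1a (76.0 against 6.91 CPM) on the expanded side. On the single side they were Eno3 (23.2-fold), Chchd10 (14.8-fold), Itm2a (9.91-fold) and Cd27 (8.80-fold). These ratios compared 76261552 UMIs of 7818 expanded cells with 28232031 UMIs of 1369 single cells, whose median depths were 7597.5 and 17904 UMIs. Within the 5 clusters with at least 20 cells of each class, weighted equally, all 30 genes kept their direction with smaller ratios, from a log2 of -4.47 for Klra7 to -0.54 for Nr4a1 and from 0.46 for Serpinb1a to 1.92 for Cdkn2a. After thinning and with each clonotype weighted equally, all named genes higher in expanded cells had smaller ratios, beyond counting error. In that order, the log2 ratio of Ifitm3 went from 4.65 to 3.67 and 3.63. That of Ifitm1 went from 4.24 to 2.95 and 2.97, and that of Cxcr6 from 3.56 to 2.51 and 2.32. Single-side ratios went both ways, with Klra7 from -10.06 to -12.46 and -10.30 but Tcf7 from -3.59 to -3.37 and -3.26. With clonotypes of 2 cells or more counted as expanded, the log2 ratio of Klra7 went from -10.06 to -4.57 and that of Dapl1 from -7.05 to -4.35. Ly49 genes are related members of 1 family, and it was not tested whether each UMI was given to the right member.

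**Figure D3:**
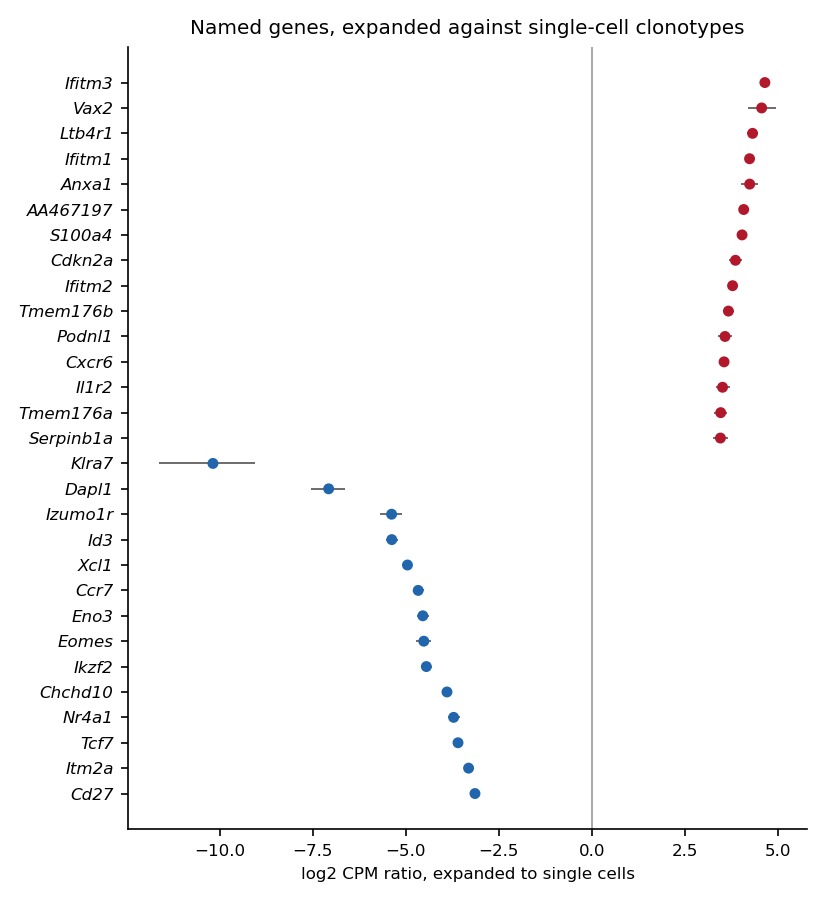
Log2 ratio of CPM in expanded to single cells (horizontal axis) for genes named by the fixed rule, with 95% intervals for counting error. Ifitm3 lies highest at 4.65, and Klra7 lies lowest of the genes that were higher in single cells.

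By list, the regulatory CD8 genes lay farthest toward the single cells, but this rested on their Ly49 genes. Their median log2 ratio of expanded to single cells was -5.15 over 8 of 13 members, below all of 10000 random lists (percentile 0). Of these 8, 4 were Ly49 genes, related members of 1 family that may not be independent. With these 4 summed as 1 member the median was -0.22 (percentile 26.1), and without them -0.20 (percentile 26.8). Klra7 had the lowest ratio and Ikzf2 (log2 -4.44) lay above the median, while the interleukin-2 receptor genes Il2ra (181 against 210 CPM) and Il2rb (469 against 338 CPM) differed little, and the summed list, in which those genes dominate, had a log2 ratio of -0.35 that was 0.18 within clusters. The Ly49 genes Klra1 (0.275 against 49.5 CPM) and Klra6 (3 against 779 UMIs) were singled out after their values were seen. Also toward the single cells lay the NK cell list (-2.15, 3 members, percentile 0.01). Its sum, mostly Gzma, was 420 against 185 CPM and so higher in expanded cells. The TCR-induced and tolerance-associated (-1.50, 11 members, percentile 0), innate-like receptor (-1.41, 6 members, percentile 0) and activation lists (-1.20, 11 members, percentile 0) lay on the same side. Klrk1, the gene of the NKG2D receptor, stood at 45.1 against 153 CPM but Klrc1 of the innate-like receptor list at 220 against 79.6. Dgka of the TCR-induced and tolerance-associated list stood at 125 in both, Irf8 at 23.3 against 120 and Tnfrsf9 at 167 against 394. The S phase list (-0.76, percentile 0.01), the inhibitory receptor list (-0.72, percentile 0.17) and the memory or naive list (-0.47, percentile 1.53, mean -1.71) followed, with Cdc6 at 25.7 against 49.0 CPM, Lag3 at 50.2 against 115 and Ctla4 at 40.2 against 137. Of the same lists Rrm2 (349 against 322 CPM) and Havcr2 (44.6 against 9.21 CPM) went the other way.

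Toward the expanded cells lay the interferon response list (1.72, 5 members, percentile 99.97), with Isg15 at 29.1 against 7.79 CPM and Isg20 at 58.2 against 11.1. The cytotoxic effector list had a median of 1.12 (15 members, percentile 100) and members on both sides: Gzma stood at 401 against 108 CPM and Gzmc at 61.0 against 28.0, but Ccl3 at 18.3 against 58.1 and Ccl4 at 43.9 against 110. The p53 and death list (0.65, percentile 99.92) included Cdkn1a at 272 against 69.6 CPM, and the virtual memory list (0.52, percentile 98.62) included Ly6a at 1750 against 322 but Eomes on the single side. CD4 T cell markers had a median of 3.20 and a mean of 1.12 (4 members, percentile 99.99), with Tnfrsf25 at 51.0 against 4.92 CPM but Izumo1r at 1.32 against 55.0, and the monocyte or macrophage list a median of 2.10 (2 members, percentile 99.15), with Ccr2 at 260 against 26.0 CPM. Cd4 itself stood at 1.18 against 0.638 CPM. The dendritic cell list had 2 measured members (1.29, percentile 97.51), and Cd74 stood at 29.3 against 30.4 CPM. Medians were 0.41 for cytokines (percentile 95.85, mean 1.40), 0.40 for CD8 T cell markers (percentile 91.57), 0.33 for resident memory (percentile 87.63, mean -0.18), 0.20 for G2/M (percentile 89.96) and 0.17 for glycolysis genes (percentile 87.46). They were 0.00 for chemokines (percentile 57.5, mean -0.68), -0.04 for the single measured plasma cell gene (percentile 53.26), -0.07 for T cell fate transcription factors (percentile 33.22, mean -1.16, with Eomes, Tcf7, Id3 and Ikzf2 far higher in single cells), -0.17 for stress genes (percentile 26.29) and -0.49 for the single measured B cell gene (percentile 13.5). The gamma-delta T, NKT, granulocyte, erythroid and platelet lists had no member of 5 CPM, and their sums were 2.78, 5.05, 1.14, 0.144 and 0.302 CPM in expanded cells.

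The Ly49 and Helios signals were also seen cell by cell. A UMI of any Ly49 gene of the fixed list was found in 26.2% of single cells (23.9 to 28.6) and in 0.729% of expanded cells (0.553 to 0.944). After thinning to 3000 UMIs the shares were 18.8% (16.8 to 21.0) and 0.404% (0.275 to 0.573), with 13 single and 147 expanded cells too shallow to be kept. In cluster 11, which was led by genes of antigen presentation and the B lineage, 0 of 30 cells had such a UMI at a median depth of 8028.5 UMIs. In so few cells this allows up to 10%. Ikzf2 was found in 58.3% of single cells (55.6 to 60.9) and 3.99% of expanded cells, and after thinning in 28.8% and 1.75%, with 1 of 30 cells in cluster 11 (3.33%, 0.0844 to 17.2). For both, the share in expanded cells was not separable from that in cluster 11. Cd8b1 was found in 98.9% of expanded and 91.2% of single cells, and after thinning in 87.2% and 68.4%, whereas Cd8a went the other way, with 80.8% and 94.3%, and 56.7% and 67.3% after thinning. In cluster 11, 12 of 30 cells had a Cd8b1 UMI (22.7% to 59.4%) and 9 a Cd8a UMI. Of its 30 cells, 6 had a paired TCR, 5 of them of expanded clonotypes. Cluster 11 thus held T cell RNA and was not a clean background for the shares above and below. Foxp3 was found in 34 of the 36 cells of cluster 10 (median depth 10837 UMIs) and in 0 of 30 cells of cluster 11, which allows up to 10%. Of the 36 cells, 33 had a Cd8b1 UMI and 12 a Cd4 UMI, and Cd4 stood at 43.3 CPM there against 2.31 or less in clusters 1 to 9. Of the same 36 cells, 18 (50%, 32.9 to 67.1) had 2 or more TRB contigs of any confidence, so many of these barcodes may hold 2 cells. After thinning, Cd8b1 was found in 22 of 33 cells of cluster 10 (48.2% to 82.0%) and in 9 of 24 of cluster 11 (18.8% to 59.4%), and these intervals overlapped. Over the clonotype classes Foxp3 was found in 2.41% of single and 1.06% of expanded cells, both under the limit from cluster 11. These shares became 0.811% (0.406 to 1.45) and 0.5997% (0.439 to 0.799) after thinning.

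Expanded clonotypes used some V genes more than single clonotypes did. TRBV12-1 was used by 29.2% of expanded clonotypes (23.7 to 35.2) and 12.6% of single ones (10.9 to 14.5), and TRBV13-1 by 16.7% (12.4 to 21.9) and 8.25% (6.85 to 9.84). TRBV12-2 and TRBV29 went the other way, with 7.004% of expanded clonotypes against 15.6% of single ones and 1.95% against 7.16%. TRBV13-3 was used by 9.34% and 8.47%. TRAV12-2 was used by 12.8% of expanded clonotypes (9.01 to 17.6) and 5.11% of single ones (4.01 to 6.42), whereas TRAV13N-4 was used by 1.95% (0.635 to 4.48) and 6.06% (4.86 to 7.46). The intervals overlapped for TRAV3D-3 (1.95%, 0.635 to 4.48, and 4.75%, 3.68 to 6.01), for TRAV6-6 (2.72%, 1.10 to 5.53, and 4.82%, 3.75 to 6.09) and for TRAV9N-3 (3.11% and 3.51%). Over all clonotypes TRBV12-1 was used by 15.8%, and over cells by 33.4%. The mouse TRAV locus holds duplicated, near-identical genes, so the choice among such copies is uncertain.

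**Figure D4:**
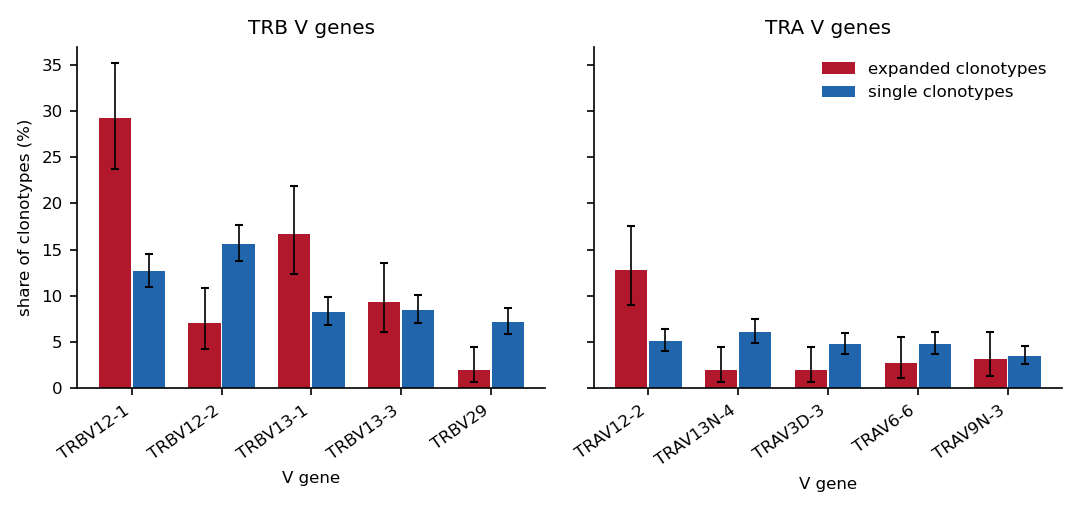
Share of clonotypes in percent (vertical axis) that used each of the 5 most frequent TRBV and TRAV genes (horizontal axis), for expanded and single clonotypes, with exact 95% binomial intervals as error bars. TRBV12-1 stands at 29.2% of expanded and 12.6% of single clonotypes.

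Different nucleotide sequences gave the same CDR3 beta amino acid sequence in 34 cases, 20 of which included an expanded clonotype. Apart from the TRBV1 group below, it was not tested whether sequence errors of 1 clonotype gave some of them. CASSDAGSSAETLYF, with TRBV13-1, was encoded by 4 nucleotide sequences in 136 cells, and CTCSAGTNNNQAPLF, with TRBV1, by 3 nucleotide sequences in 217 cells. Of 244 expanded TRB nucleotide chains, 21 shared their amino acid CDR3 with another expanded chain, against a mean of 1.03 and a highest value of 6 in 100 equal-sized draws of single chains. Of 233 expanded CDR3 beta sequences, 14.6% (10.3 to 19.8) had another 1 residue away, against a mean of 2.46% in draws of single chains. In draws matched on V gene the mean was 4.47% (lowest 1.56, highest 7.51). Neighbours count each other, so they are not independent and the interval on 14.6% is too narrow. CDR3 lengths were alike, with a mean of 13.7 residues in expanded and 13.8 in single TRB chains (SDs 1.63 and 1.63 over 257 and 1369 clonotypes).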

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

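Leaving out barcodes by TRB contigs of any confidence, keeping every productive contig, and the levels in small clonotypes were chosen only after the data were seen.

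A signal appeared in TCR contigs that the report's comparisons did not use, although an alternative with every productive contig did. In 2282 analysed barcodes that the deposited TCR table did not call cells there were 5434 productive TRB contigs of 3 or more UMIs. Of these barcodes, 1950 (85.5%, 83.9 to 86.9) had 2 or more such contigs, and their median depth was 18390 UMIs against 9389 over all analysed cells. The TRB of an expanded clonotype was found in 4015 of the contigs (73.9%, 72.7 to 75.1). By cluster, 2 or more TRB contigs of any confidence were found in 30.4% of cells of cluster 3 with a TRB contig, in 14.2% of cluster 9, in 16.3% to 19.7% of clusters 2, 4, 6 and 7, in 10.5% of cluster 5 and in 6.79% of cluster 1. They were also found in 10.3% of cluster 8, in 18 of 36 such cells of cluster 10 (50%, 32.9 to 67.1) and in 4 of 11 of cluster 11. Many of these barcodes may hold 2 cells, and 10757 cells remained when all barcodes with 2 or more TRB contigs of any confidence were left out. Barcodes that are not called cells entered the cluster sizes and list levels but had no paired TCR, and so entered the comparisons of clonotypes only in that alternative.

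Klra7, Dapl1, Id3 and others of the 15 genes named by the rule were higher in single than in expanded cells. A cell cycle difference was argued against, since the median log2 ratio of the 15 genes stayed at -4.90 within quartiles of cycling gene CPM. With every productive contig kept, only 5.64% (4.69 to 6.71) of paired cells in clusters 3 and 9 were expanded. This argued against barcodes of expanded clonotypes left out by the V(D)J cell call, but only for the chains with most UMIs. In a barcode of 2 cells, expanded chains with fewer UMIs would not count, so the test cannot decide for those. In small clonotypes Klra7 stood at 30.6 CPM (27.4 to 34.2) and was found in 25 cells of 14 clonotypes, so it was not limited to clonotypes seen once, and 30.5% of small cells lay in clusters 3 and 9, against 81.0% of single and 1.14% of expanded cells. In the 7740 expanded and 1356 single cells with 1 TRB chain, the median log2 ratio of the 15 genes was -4.55. Barcodes with a second TRB chain were thus argued against as the source of these ratios. The design has 1 group and no biological explanation was tested. Sorting, culture survival and droplets of 2 cells in which 1 TRB chain was found were left open.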

How the results depend on the processing

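The alternatives with any-confidence contigs, the highest Scrublet scores or clusters 10 and 11 left out, clonotypes without V genes, and Ly49 genes summed or left out, were chosen only after the data were seen. Cells analysed were 13654 with doublets kept, 12114 without the highest Scrublet scores and 10757 with doublets taken from TRB contigs of any confidence, against 12787. The largest cluster held 41.5% of cells at resolution 0.3, 15.2% at 1.0 and 24.0% without cell cycle genes, against 28.3%. The regulatory CD8 list level in clusters 3 and 9 was 1.38 times that of the other 6 clusters without ribosomal protein and mitochondrial genes, against 1.30. The paired share was 74.7% with contigs of 3 or more UMIs, 79.2% with doublets kept and 92.1% with every productive contig of 3 or more UMIs, against 77.8%. The expanded share, 78.6%, was 86.2% from 2 cells, 71.7% from 10 cells, 79.4% by TRB alone, 77.8% by the deposited clonotype ID, 77.6% with doublets kept and 72.1% with every productive contig. In clusters 3 and 9 it was 22.4% from 2 cells, against 6.22%. The regulatory CD8 median of expanded against single cells, -5.15, was -4.66 with clonotypes weighted equally, -3.76 with expanded from 2 cells, -2.24 within clusters, -0.22 with its Ly49 genes summed as 1 member and -0.20 without them, since these were 4 of its 8 members. Its sum turned from -0.35 to 0.18 within clusters, and the cause was not tested. TRBV12-1 took 33.4% of cells against 15.8% of clonotypes, since large clonotypes count once in the latter. None of the 30 named genes changed direction in 7 alternatives, of which equal weights and leaving out the largest clonotype could show no change, since the naming rule required it: all 30 moved beyond counting error within clusters, 29 with equal weights, 24 after thinning, 21 from 2 cells, 2 without clusters 10 and 11, and 0 without the largest clonotype or the highest Scrublet scores. Depth limits genes near 1 UMI per cell and shares in the 30 to 36 cells of clusters 10 and 11.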

Other observations

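The clonotype behind Il17a, the genes Cd40lg and Zbtb7b, and all tests of the TRB pairs and of the TRBV1 group were chosen only after their results were seen.

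Il17a, the gene of interleukin-17A, came from few cells. Of 2929 Il17a UMIs, 1326 (45.3%) were in a single clonotype of 30 cells with TRAV16D-DV11 and TRBV4, the clonotype of rank 62 by size, and 986 were in 1 cell of it. Its 14 cells in cluster 3 had 2898 CPM of Csf2 (2734 to 3070) and 180 CPM of Tmem176b (141 to 227), against 73.3 and 18.4 CPM in the rest of that cluster. They had 5.01 CPM of Xcl1 (0.607 to 18.1) and 5.01 CPM of Id3, where the rest of cluster 3 had 276 and 154. Il17a UMIs were found in 62 cells in all, 27 of them with 5 or more, so the ratio of expanded to single cells for this gene (21.6 against 0.248 CPM) rests on few cells.

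Cd40lg and Zbtb7b, usually tied to CD4 T cells, were higher in expanded than in single cells, although Cd4 was low in both and Izumo1r of the same list was higher in single cells. Cd40lg stood at 25.8 CPM in expanded and 2.34 in single cells, and Zbtb7b, which encodes a factor of CD4 lineage choice, at 22.9 and 2.76. In cluster 1 they reached 38.6 and 31.3 CPM, with a Cd40lg UMI in 18.04% of cells (16.8 to 19.3) at a median depth of 4987 UMIs. In cluster 11, with a median depth of 8028.5 UMIs, 2 of 30 cells had a Cd40lg UMI (6.67%, 0.818 to 22.1) and 0 had a Zbtb7b UMI, which allows up to 10%. The Cd40lg share in cluster 1 alone was not separable from that in cluster 11. That cluster also held cells with a paired TCR, so it was no clean background. Cd40lg stood at 0.687 CPM in cluster 9. A Cd40lg UMI occurred in cells of 311 clonotypes, 117 of them cells of the largest clonotype. Cd4 UMIs were found in 0.844% of expanded cells (0.653 to 1.07), in 0.950% of single cells and in 0 of the 30 cells of cluster 11, which allows up to 10%.

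A group of 13 TRBV1 clonotypes with CDR3 beta sequences ending in GTNNNQAPLF held 307 cells (3.09% of paired cells), 304 of them in clusters 1, 2, 4, 5, 6 and 7 and 0 in clusters 3 and 9. Of the 13, 12 paired with a TRAV16 family gene and TRAJ42, as did 4 of 1912 other clonotypes (0.209%), and 6 were expanded, the largest with 104, 90 and 74 cells. Sequence errors of 1 large clonotype were argued against as the cause of the whole group, since 7 of the other members differed from the largest by 3 or more nucleotides over both CDR3s. Of these 7, 1 paired with TRAV7-4 and TRAJ33 instead. The remaining members differed by less, 1 of them by 0, so errors or a split by V gene stay possible for those. Differences were taken only from the largest member, so errors of the other large members were not tested. The CDR3s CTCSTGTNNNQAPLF and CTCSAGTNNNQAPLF of this group also occurred together in 29 barcodes left out for 2 TRB chains. That was 69.5 times as often as chance would give, and 100% of these barcodes had 1 TRA. The reason was not tested. A clonotype split between near-identical TRAV16 genes was argued against as the cause of the whole group, since 12 members were left when V genes were not used. Separate rearrangements chosen for a shared receptor shape may account for the group, a hypothesis for which the antigen was not analysed here.

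Among the 867 barcodes left out for 2 TRB chains, 391 pairs of chains occurred, 305 of them once and 34 in 5 or more barcodes. Of the 10 most frequent pairs, 4 (94 barcodes) had chains found alone in 4 barcodes or fewer, and 93 of these barcodes had the pair's most frequent TRA. Chance droplets of 2 cells were argued against, since even at the highest excess over chance of the other 6 pairs (73.7-fold) none of these 4 would be expected in more than 0.953 barcodes, against 15 to 31 observed. The 4 pairs were picked because their chains were rarely alone, but in 100 random pairings of all chains no pair picked this way occurred in more than 1 barcode. Free TCR RNA of a large clonotype was argued against, since the second chain had 60.4% (median) of the first chain's UMIs. The lowest of the 4 pairs had 29.2%, below the median of 32.4% in the other 6 pairs. The 4 pairs were not alike: in the pair of 15 barcodes only 13.3% had 1 TRA, against 100% in each of the others. Clones that carry 2 productive TRB chains may account for these 94 barcodes, a hypothesis that was not tested apart from this. The other 6 pairs (147 barcodes) joined chains that were each common alone and occurred 14.6 to 73.7 times as often as chance would give.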
